A study of Mus musculus with 12 samples.

How the data were processed

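Reduced representation bisulfite sequencing (RRBS), which reads cytosine methylation mainly in CpG-rich fragments of the genome, was performed on DNA from cultured mouse prostate fibroblasts. The 12 libraries formed 4 groups of 3: PBS, BuOE, PBS with radiation (PBS+RT) and BuOE with radiation (BuOE+RT). Groups were taken from the treatment label and replicate numbers from the sample titles. Per the labels' protocols, irradiated male C57BL/6 mice received a pelvic dose of 37.5 Gy, given as 7.5 Gy on each of 5 days at 1.2 Gy per minute, and fibroblasts were isolated 2 months after radiation and cultured for 3 days. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

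The deposited values are percent methylation at single CpG positions, from 0 to 100, with 1 line per reported position. Per the submitters' processing notes, Trim Galore, cutadapt 2.9, Bismark, methylKit 1.30.0, R 4.3.0 and the GRCm39 mouse genome build were used; the roles and settings of these tools are not given in the sources used here. The deposited percent values carry no read count, so the depth behind each percent is unknown, and no interval that needs a depth was computed. The libraries reported 2631884 (BuOE+RT replicate 3) to 6680350 positions (BuOE replicate 3). From 92.4% to 95.4% of the positions of a library were at exactly 0 or 100%. Of the 19706815 distinct positions, 43.0% were reported in exactly 1 library and 112756 in all 12.

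Before the data were examined, a count model of methylated and unmethylated calls with a coverage minimum had been chosen. Because the values are percents without counts, that model was replaced by limma on percent means, and the coverage minimum by the requirement that a position be reported in all 12 libraries. The gene table at hand belongs to another build, GRCm38.p6, and coordinates were not carried between builds. Promoters, gene lists, cell type markers and gene names were therefore not analysed here, and regions are given by their GRCm39 coordinates.

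Global methylation of a library was the mean percent over the 112479 positions of the autosomes and the X chromosome reported in all 12 libraries. Non-overlapping 500-bp tiles with at least 2 such positions and a pooled level from 2 to 98% were tested (19816 of 21067 tiles). The mean percent of each tile was fitted in limma 3.58.1 (R 4.3.3) with 1 level per group, all 12 libraries sharing the estimate of the spread, with empirical Bayes moderation and a mean-dependent prior. A tile was called at a Benjamini-Hochberg adjusted p under 0.05 with a difference of at least 10 percentage points. The 4 pairwise comparisons, the interaction (radiation effect under BuOE minus radiation effect under PBS) and the averaged radiation and BuOE effects were tested. By the rule fixed for tiles, the 3 largest called rises and the 3 largest called falls with library ranges that did not overlap were to be named, and the fixed rule for genes could not be applied. No tile was called, so the pair of tiles with the smallest unadjusted p was named instead and the tile rule was carried over to windows; both choices were made after the data were seen.

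Several measures were added after the data were seen, because few positions were common to all libraries. The position-adjusted level was the library level left after each position's own level was removed, by least squares with position and library terms, over the 11208740 positions of the autosomes and the X chromosome reported in at least 2 libraries. The same fit was made within classes of bins, within chromosomes and within 1-Mb windows. Values over all reported positions are plain means of the positions each library reported, with no position level removed. A position's class was the number of distinct positions that any library reported in its 500-bp bin, in 6 classes. Bins with few such positions can be poor in CpGs or seldom sequenced, which was not separated here: at 1 to 4 positions per bin, 4061 of 4765608 positions were reported in all libraries, and at 50 or more, 31728 of 1584290. The 2254 windows of 1 Mb with at least 200 reported positions in every library were tested in limma and called at an adjusted p under 0.05. The spread of a difference between libraries is given as a standard error (SE) from the variance pooled over the 4 groups.

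Library levels were compared with exact two-sided permutation tests. With 3 libraries against 3 the smallest p is 0.1. Averaged effects were tested over the 400 arrangements of labels within the levels of the other factor, where the smallest p is 0.005. The interaction was tested with 100000 permutations of the residuals of the model without it. Benjamini-Hochberg adjustment covered 6 comparisons for a library level, with the interaction adjusted over 7, and 6 classes for each comparison of classes of bins.

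The limma step was tested on simulated data in which 200 features were shifted upward in the PBS+RT libraries. Shifted tiles were drawn only from those with a lower mean level, so the tile rates do not cover highly methylated tiles or losses. For the comparison of PBS+RT with PBS, among 19816 tiles it recovered 1.49% of shifts of 10 points, 38.8% of 20 points and 69.7% of 40 points. Among 2254 windows it recovered 7.46% of shifts of 2 points, 71.6% of 4 points and 100% of 8 points. Computations other than limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives covered the tile width, single positions, the level filter, thresholds, scale, the position set, window size, removal of each library's mean from its windows, a replicate block and each library left out.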

Results

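DNA methylation was measured by RRBS in fibroblasts grown from mouse prostates, with and without earlier pelvic radiation and with PBS (phosphate-buffered saline) or BuOE. BuOE is read here as the compound of the series title, BMX-001, a redox-active manganese porphyrin under test as a radioprotector. The title gives the study's question as whether BMX-001 given 3 weeks after radiation reverses radiation-induced fibrosis, the scarring driven by matrix-producing fibroblasts. The labels do not say how or when BuOE was given, with or without radiation. The 4 groups held 3 libraries each. The libraries reported between 2631884 and 6680350 CpG positions, and the read depth behind each percent is unknown. Only 112479 positions on the autosomes and the X chromosome were reported in all 12 libraries, so a position-adjusted level over 11208740 positions reported in at least 2 libraries is given beside the level over those common positions.

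**Figure D1:**
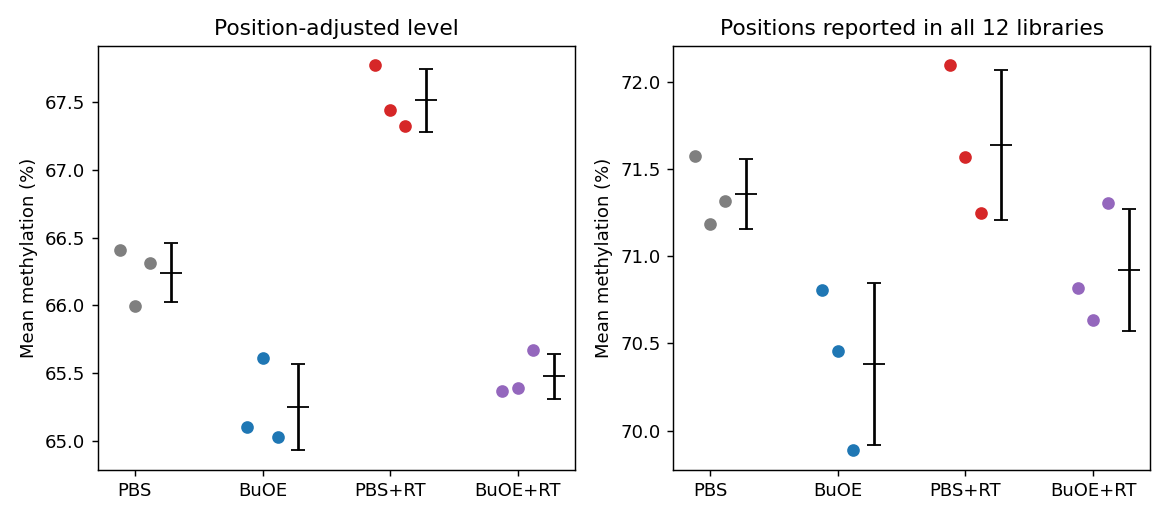
Mean methylation in percent of each library (points) by group, with the group mean and SD (bars, n = 3), for the position-adjusted level (left) and for positions reported in all 12 libraries (right); the vertical axes do not start at 0. On the left the 3 PBS+RT libraries, from 67.32 to 67.77%, lie above the libraries of the other groups, and both BuOE groups lie below PBS.

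Among libraries labelled PBS, those from irradiated mice had the higher position-adjusted methylation. This comparison asks what radiation left in the fibroblast methylome 2 months later. The position-adjusted level was 67.51% ± 0.23 (SD, n = 3) in PBS+RT and 66.24% ± 0.22 (SD, n = 3) in PBS, a difference of 1.27 points (SE 0.196) with library ranges that did not overlap. All 19 autosomes, which share the same libraries, were higher, from 1.08 points on chromosome 19 to 1.43 points on chromosome 1. The X chromosome was higher by 1.13 points. The difference was larger in bins with few reported positions, which can hold few CpGs or be seldom sequenced. In 500-bp bins with 1 to 4 reported positions the level was 75.50% ± 0.15 in PBS+RT and 72.95% ± 0.28 in PBS, a difference of 2.55 points (SE 0.279). In bins with 50 or more positions, a density typical of CpG islands, the levels were 12.26% ± 0.44 and 12.13% ± 0.25, a difference of 0.133 points (SE 0.256). Over the positions common to all libraries these differences were 1.53 points (SE 0.402) and −0.303 points (SE 0.454). At 30 to 49 positions the difference was 0.363 points with the position-adjusted level and −0.0559 points over the common positions, and over all reported positions it was −1.73 points there and −1.13 points at 50 or more.

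Among 2254 windows of 1 Mb, 109 rose after radiation under PBS and 0 fell (limma, adjusted p under 0.05), on the 19 autosomes and the X chromosome, with a median rise of 3.93 points. The largest called rises were on chromosome 8 at 98000001 to 99000000 (67.5% ± 3.77 to 76.4% ± 2.26; limma, adjusted p = 0.0299), chromosome 2 at 159000001 to 160000000 (70.2% ± 1.65 to 78.5% ± 1.13; limma, adjusted p = 0.0179) and chromosome 3 at 155000001 to 156000000 (70.2% ± 2.97 to 78.3% ± 0.984; limma, adjusted p = 0.0243). These windows held few positions, 1136, 2635 and 1144 in this order, against a median of 3393 among the 109 called. Over all windows, which share the same libraries, 88.5% were higher in PBS+RT. The exact permutation test of the position-adjusted level gave p = 0.1 (adjusted p = 0.12), the smallest that 3 libraries against 3 can give, and over the positions common to all libraries the difference was 0.280 points (SE 0.306, exact permutation p = 0.5). The count of windows was 1 after removal of each library's mean, 4 with plain means of the reported positions, 0 in windows of 100 kb and 36 with only the 6 libraries of the comparison; with 1 library left out it was 18, 15 and 41 without PBS replicates 1, 2 and 3, 9, 16 and 20 without PBS+RT replicates 1, 2 and 3, 43 without BuOE replicate 3, and 54 and 51 without BuOE+RT replicates 1 and 2.

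Under BuOE, irradiated and unirradiated fibroblasts had nearly the same position-adjusted level. This comparison asks what radiation left behind in the BuOE groups. The level was 65.48% ± 0.17 (SD, n = 3) in BuOE+RT and 65.25% ± 0.32 (SD, n = 3) in BuOE, a difference of 0.228 points (SE 0.196, exact permutation p = 0.3). The difference was −0.387 points (SE 0.279) in bins with 1 to 4 positions and 0.526 points (SE 0.236) in bins with 20 to 29 positions, but over the common positions it was 0.642 points (SE 0.402) in the former and 0.559 points (SE 0.417) in the latter. None of the 2254 windows was called by limma, with 154 at an unadjusted p under 0.05 and 2, both lower, called without BuOE replicate 3, and 56.5% of the windows were higher in BuOE+RT. Over the common positions the difference was 0.536 points (SE 0.306, exact permutation p = 0.2), and it was −0.165 points over all reported positions.

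Without radiation, libraries labelled BuOE had a lower position-adjusted methylation than those labelled PBS. This comparison sets the BuOE and PBS groups side by side without radiation. The position-adjusted levels of 65.25% ± 0.32 and 66.24% ± 0.22 differed by −0.991 points (SE 0.196), with ranges that did not overlap. All 19 autosomes, which share the same libraries, were lower, from −1.06 points on chromosome 11 to −0.775 points on chromosome 13. In the position-adjusted level, classes of bins with up to 29 reported positions differed by nearly equal amounts, from −1.06 points (SE 0.279) at 1 to 4 positions to −1.19 points (SE 0.236) at 20 to 29 positions, against −0.332 points (SE 0.256) at 50 or more. Other position sets did not give equal amounts: the common positions gave −1.38, −1.40, −0.821 and −1.27 points in the 4 classes up to 29 and −0.665 points at 50 or more, and all reported positions −1.39, −1.48, −1.81 and −2.14 points and −1.47 points. Of the windows 81.8% were lower under BuOE, but limma called 0 of 2254, with 385 at an unadjusted p under 0.05 and 3, all lower, called without PBS+RT replicate 1. The exact permutation p was 0.1 for the position-adjusted level and 0.1 for the common positions, where the difference was −0.974 points (SE 0.306).

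After radiation, BuOE libraries had a lower position-adjusted level than PBS libraries, and this was the largest of the 4 pairwise differences in that level. The comparison asks how the BuOE and PBS groups differed among irradiated mice. The levels of 65.48% ± 0.17 in BuOE+RT and 67.51% ± 0.23 in PBS+RT (SD, n = 3) differed by −2.03 points (SE 0.196), and the ranges did not overlap. All 19 autosomes, which share the same libraries, were lower, from −2.38 points on chromosome 12 to −1.75 points on chromosome 19. The X chromosome differed by −2.42 points. The difference followed the number of reported positions per bin. It was −3.999 points (SE 0.279) in bins with 1 to 4 positions (71.50% ± 0.15 against 75.50% ± 0.15), −2.86 points (SE 0.242) at 5 to 9 positions, −2.11 points (SE 0.232) at 10 to 19, −1.55 points (SE 0.236) at 20 to 29, −0.821 points (SE 0.205) at 30 to 49 and −0.313 points (SE 0.256) at 50 or more. Over the common positions the differences were smaller, at −2.26 points (SE 0.402), −1.80 points, −1.21 points, −0.688 points, −0.333 points and 0.0266 points in the same order.

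**Figure D2:**
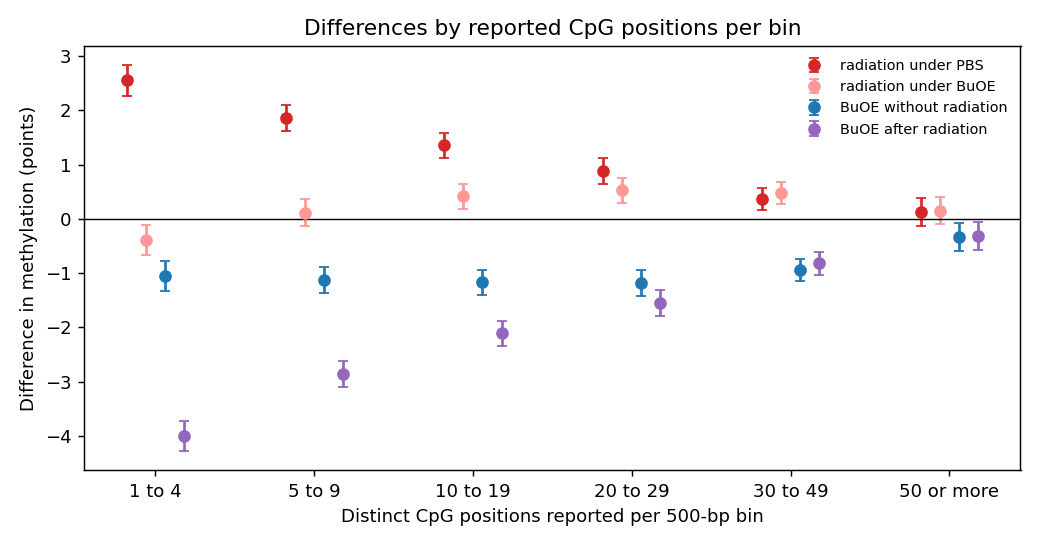
Difference in position-adjusted methylation in percentage points (points, with the pooled SE as bars, 3 libraries per group) against the number of distinct CpG positions reported in a 500-bp bin, for the 4 pairwise comparisons. Radiation under PBS goes from 2.55 points at 1 to 4 positions to 0.133 points at 50 or more, and BuOE after radiation goes from −3.999 to −0.313 points.

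In windows of 1 Mb, 930 of 2254 were lower and 1 higher in BuOE+RT than in PBS+RT (limma, adjusted p under 0.05). The largest called falls were on chromosome 15 at 16000001 to 17000000 (77.9% ± 2.86 in PBS+RT to 66.5% ± 5.14 in BuOE+RT; limma, adjusted p = 0.00546), chromosome 18 at 17000001 to 18000000 (80.8% ± 0.473 to 71.1% ± 4.32; limma, adjusted p = 0.00534) and chromosome 11 at 92000001 to 93000000 (67.7% ± 1.87 to 58.3% ± 2.23; limma, adjusted p = 0.00161). These windows held few positions, 1137, 1391 and 1373 in this order, against a median of 4182 among the 930 called lower. The 1 window called higher, on chromosome 11 at 22000001 to 23000000 (65.8% ± 1.26 to 68.0% ± 0.966), lay close to the threshold (limma, adjusted p = 0.0428). No window was called higher with a minimum of 3 points, plain means, bins of under 10 positions only or the 6 libraries of the comparison only, nor without PBS+RT replicate 1, 2 or 3 or BuOE+RT replicate 2 or 3. Over all windows, which share the same libraries, 97.3% were lower in BuOE+RT. The exact permutation p of the position-adjusted level was 0.1, the smallest possible. Over the common positions the difference was −0.718 points (SE 0.306, exact permutation p = 0.2), with overlapping ranges. That is smaller in size than the −0.974 points (SE 0.306) of BuOE without radiation over the same positions. The count of called windows was 4 (1 higher, 3 lower) after removal of each library's mean, 2 in windows of 100 kb (1 higher, 1 lower) and 519 with a minimum of 3 points. The count was 490 without BuOE+RT replicate 1, 500 without PBS+RT replicate 1, 545 without BuOE+RT replicate 2 and 585 without PBS+RT replicate 2.

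**Figure D3:**
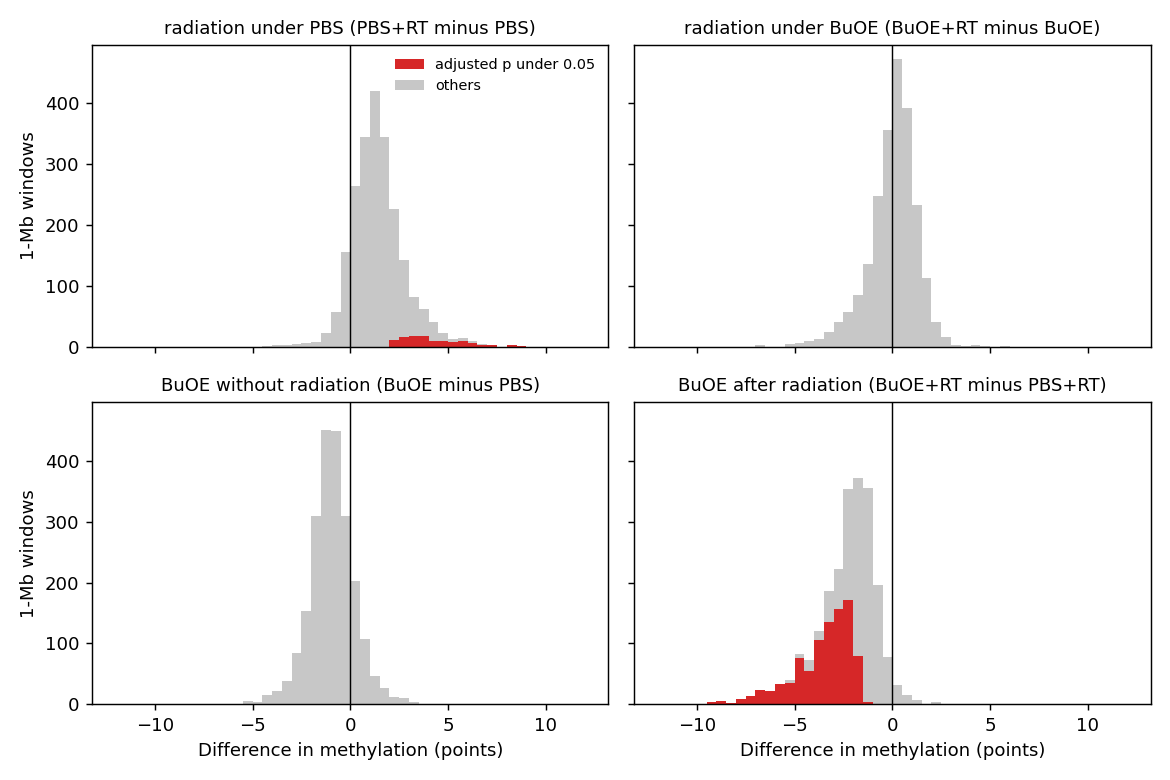
Number of 1-Mb windows against the difference in mean position-adjusted methylation in percentage points, in bins of 0.5 points, for the 4 pairwise comparisons (2254 windows each); red marks windows at a limma adjusted p under 0.05. Called windows number 109 for radiation under PBS and 931 for BuOE after radiation, with 0 in the other 2 panels.

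The radiation effect differed between PBS and BuOE in the position-adjusted level. The interaction, radiation under BuOE minus radiation under PBS, was −1.04 points (SE 0.277, permutation p = 0.00494, adjusted p = 0.0175). It was negative on all 19 autosomes, which share the same libraries, from −1.37 points on chromosome 14 to −0.759 points on chromosome 19. It was −2.94 points (SE 0.395, permutation p = 0.00198, adjusted p = 0.00606) in bins with 1 to 4 positions, −1.74 points (SE 0.342, adjusted permutation p = 0.00606) at 5 to 9 and −0.944 points (SE 0.328, adjusted permutation p = 0.0332) at 10 to 19. It was −0.362 points at 20 to 29, 0.119 points at 30 to 49 and 0.0193 points (SE 0.362) at 50 or more. Over the common positions none of the 3 classes with fewer than 20 positions passed, with −0.885 points (permutation p = 0.157), −0.394 points (permutation p = 0.399) and −0.389 points (permutation p = 0.404). Over all reported positions only the first passed, with −2.95 points against −1.21 points (adjusted permutation p = 0.0615) and 0.055 points. At 20 to 29, 30 to 49 and 50 or more positions the interaction was positive on these sets, but did not pass after adjustment. There it was 0.580, 0.715 and 0.692 points over the common positions and 0.888, 2.52 and 1.49 points over all reported positions. The value at 10 to 19 did not pass without any 1 of 8 libraries, which were PBS replicates 1 (−1.025), 2 (−0.826) and 3 (−0.981), BuOE replicate 2 (−0.706), PBS+RT replicates 1 (−0.789) and 2 (−0.983) and BuOE+RT replicates 1 (−0.870) and 2 (−0.926). In 30 windows of 1 Mb the interaction was called, negative in each (limma, adjusted p under 0.05), but 5 of 100 splits of the libraries, the real one included, gave as many calls. The interaction depended on the positions used: it was −0.483 points (permutation p = 0.160) over positions reported in at least 6 libraries, −1.39 points (adjusted permutation p = 0.140) over all reported positions and 0.256 points (SE 0.433, permutation p = 0.580) over the common positions. With 1 library left out 0 to 16 windows were called, fewer than 30 whichever library it was, and 2 were called with plain means and 0 after removal of each library's mean. In windows of 100 kb 1 was called, with a positive interaction.

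Averaged over radiation, BuOE libraries had a lower position-adjusted level, by a difference of −1.51 points (SE 0.139, exact permutation p = 0.005, the smallest possible, adjusted p = 0.03). Each of the 3 BuOE and 3 BuOE+RT libraries lay below each library of its PBS counterpart. In limma, 1043 windows were lower and 0 higher, against 661 without PBS+RT replicate 1, 695 without BuOE replicate 3, 541 with bins of under 10 positions only, 194 with a minimum of 3 points, 1 in windows of 100 kb and 0 after removal of each library's mean. Over the common positions the averaged BuOE difference was −0.846 points (SE 0.216, exact permutation p = 0.01, adjusted p = 0.06). In bins with 1 to 4 positions it was −2.53 points with the position-adjusted level and −1.82 points over the common positions (exact permutation p = 0.005 for both, adjusted over the 6 classes p = 0.006 and 0.0075). Adjusted over the 6 comparisons of this class instead, the former had an exact permutation p of 0.03. That p was 0.06 without PBS replicate 1 (−2.516), 2 (−2.606) or 3 (−2.466), where the test had fewer arrangements of labels. These misses alone do not show a smaller difference. Averaged over treatment, irradiated libraries had a position-adjusted level higher by 0.749 points (SE 0.139, exact permutation p = 0.015, adjusted p = 0.045) and a level over the common positions higher by 0.408 points, which did not pass the test (SE 0.216, exact permutation p = 0.085). The position-adjusted value did not pass without bins of 50 or more positions (0.863), or without BuOE replicate 1 (0.712), BuOE replicate 3 (0.694) or BuOE+RT replicate 3 (0.700). The plain means over all reported positions gave 0.531 points, which did not pass.

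Irradiated BuOE libraries were also set against unirradiated PBS libraries, the comparison closest to the reversal named in the title. The position-adjusted level of BuOE+RT differed from that of PBS by −0.762 points (SE 0.196, exact permutation p = 0.1), with ranges that did not overlap, and by −1.45 points in bins with 1 to 4 positions, again with ranges apart. Over the common positions the difference was −0.438 points (SE 0.306, exact permutation p = 0.2) and in bins with 50 or more positions −0.179 points (SE 0.256, exact permutation p = 0.4), with overlapping ranges in both. Of the 109 windows that rose after radiation under PBS, 97 were among the 930 that fell with BuOE after radiation, where independent lists would share 44.97. Both differences use the PBS+RT libraries, so part of the excess may come from those shared libraries. Across windows the correlation of the radiation difference under PBS with the BuOE difference after radiation was −0.642, against −0.496 (−0.553 to −0.443) in simulations without effects, and the covariance was −1.44 against −0.558, a difference of −0.883. The simulations drew noise independently for each window, without deviations that the windows of a library share. Their range may therefore be too narrow, and the excess is not read as a reversal.

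At the scale of 500-bp tiles no difference passed the test. Limma called 0 of 19816 tiles in each of the 7 tests, with 839 to 1060 tiles at an unadjusted p under 0.05; limma on the log2 ratio or the arcsine scale called at most 1, and with 1 library left out at most 5. The tiles with the smallest p for radiation under PBS, which did not pass and were chosen after the data were seen, were on chromosome 7 at 5096001 to 5096500 (5.56% ± 9.62 in PBS and 86.7% ± 23.1 in PBS+RT) and chromosome 4 at 43731001 to 43731500 (100% in each PBS library and 63.1% ± 3.37 in PBS+RT; limma, adjusted p = 0.269 for both). The latter tile was at 100% in each BuOE+RT library. Each of these tiles held only 2 common positions, and the read depth behind their percents is unknown. Across tiles the radiation differences under PBS and under BuOE had a correlation of −0.0076, within the −0.0214 to 0.0219 of 100 regroupings of the libraries; tiles are not independent replicates. Across windows this correlation was −0.183. The 100 regroupings ran from −0.183 to 0.183, but the real grouping and swaps of its labels were not kept out of them. Such bounds can be the real value itself, so they do not test it. Across tiles the correlation of the radiation difference under PBS with the BuOE difference after radiation was −0.529, against −0.500 (−0.517 to −0.485) in simulations without effects, and the covariance was −71.9 against −57.1, a difference of −14.7. These simulations drew noise independently for each tile. With no tile called, the share of the radiation change reversed at called tiles is undefined.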

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

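Of the tests in this part, those with the number of positions reported, with the reads per position and with positions reported by few libraries were fixed before their results were seen; the others were chosen after.

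In the position-adjusted level the effect of radiation differed between the PBS and BuOE groups, by the test of the difference itself. Over the common positions the interaction was 0.256 points (SE 0.433, permutation p = 0.580), and over all reported positions −1.392 points (adjusted permutation p = 0.140). Neither passed. The position-adjusted interaction, over positions reported in at least 2 libraries, was −1.041 points over all classes of bins. It was −2.939 points in bins with 1 to 4 reported positions, −1.739 points at 5 to 9 and −0.944 points at 10 to 19. In bins with 1 to 9 positions it was −2.178 points over positions in at least 2 libraries and −1.596 points (SE 0.341) over positions in at least 6. This argues against positions that few libraries report as the whole source there. The interaction kept shrinking, to −1.431 points (SE 0.348) with at least 8, so such positions may be part of the source. In bins with 10 or more positions it was −0.460, −0.148 and −0.011 points with at least 2, 6 and 8 libraries, so there they stay open as the source. Over all classes of bins, at least 6 libraries gave −0.483 points, which did not pass. With the number of positions reported as a covariate the position-adjusted interaction over all classes of bins was −1.136 points (SE 0.318), so a trend with that number does not account for it. A treatment-dependent response to radiation may remain as a hypothesis for bins with few reported positions, which can be CpG-poor or seldom sequenced, although over positions common to all 12 libraries the interaction was −0.885 points at 1 to 4, −0.394 at 5 to 9 and −0.389 at 10 to 19, none of which passed, and a change in the mix of cultured cells was not tested.

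Methylation was lower in both BuOE groups, by an averaged difference of −1.511 points, which was −1.493 points (SE 0.146) with the number of positions reported as a covariate and −1.424 points (SE 0.183) with the share of positions between 0 and 100%, which rises with the reads per position. Fuller bisulfite conversion in BuOE libraries would act most on weakly methylated dense bins, but averaged over radiation the position-adjusted difference in bins with 50 or more positions lay 2.207 points (SE 0.306) above that in bins with 1 to 4. Without radiation these classes differed less, at −0.332 points (SE 0.256) and −1.06 points (SE 0.279). There the common positions gave −0.665 and −1.38 points, but all reported positions −1.47 and −1.39 points. Fuller conversion therefore stays open for the difference without radiation. Over-conversion of methylated cytosines would remove a fixed share of the level: after radiation the loss at 1 to 4 positions exceeded the scaled loss at 20 to 29 by −2.422 points (SE 0.187), and by −1.65 (SE 0.306) over the common and −3.09 (SE 0.576) over all reported positions. Over-conversion alone would not give this excess. The difference after radiation also holds the rise of PBS+RT over PBS, 2.55 points (SE 0.279) at 1 to 4 positions. Over-conversion in BuOE libraries beside such a rise is therefore not excluded. Without radiation the excess was 0.122 points (SE 0.187), and −0.278 (SE 0.304) and 0.656 (SE 0.560) on those sets, each within 2 SE of the 0 that over-conversion predicts, although the losses themselves depended on the set (−1.39 at 1 to 4 and −2.14 points at 20 to 29 over all reported positions). The difference without radiation may therefore be technical or an effect of the compound, and for the larger loss after radiation in bins with few positions an effect of the compound stays a hypothesis, with a change in the mix of cultured cells untested.

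Over all reported positions, the level in bins with 50 or more positions fell with the log2 number of positions a library reported, from 16.3 to 12.8% (Pearson's r = −0.888, permutation p = 0.0002; Spearman's rho = −0.888, permutation p = 0.0003; n = 12; 6 relations, adjusted p = 0.0011 and 0.002). Without the 2 libraries farthest from the median r was −0.896, and within groups it was −0.890. With each position's own level removed r was −0.369 (permutation p = 0.239; without the 2 farthest libraries −0.196), but rho was −0.462 (permutation p = 0.135) and r within groups −0.455, both just over the halved size that was set as the bound. Differences in which positions each library reports may be a source of part of the trend, and whether they are the whole of it stays open with 12 libraries; no biological explanation was tested.

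Other splits of the same libraries were counted for each limma result. For 1-Mb windows, 1 of 10 splits reached the 109 calls of radiation under PBS and the highest other gave 0, and 1 of 10 reached the 931 calls of BuOE after radiation, with 0 as the highest other. For radiation under BuOE and BuOE without radiation, with 0 calls each, all 10 splits gave as many, and the highest others were 0 and 1. These 10 splits are too few for a share under 0.05. For the averaged BuOE effect 1 of 100 splits, the real one, reached 1043 calls, and the highest other gave 690. So many calls were therefore rare among regroupings of these libraries, which may be technical repeats. For the interaction 5 of 100 splits reached 30 calls, with a highest other of 416, so chance is not excluded. A split with that many calls points to a structure of the libraries, which can be the group differences themselves, since these splits mix all 12 libraries; its source was not tested. For the averaged radiation effect, with 0 calls, all 100 splits gave as many and the highest other gave 30. For tiles, with 0 calls in every test, all 10 splits of each pairwise comparison and all 100 of the interaction and the averaged effects gave as many. The highest other was 1 for radiation under BuOE, BuOE without radiation, the interaction and averaged BuOE, and 0 for radiation under PBS, BuOE after radiation and averaged radiation.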

How the results depend on the processing

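Read depth is unknown, so which differences depth hides cannot be stated. Alternatives for the position-adjusted level, classes of bins and windows, other position sets for global methylation, the arcsine, log2 ratio and positions-per-tile settings of tiles, windows for the correlations, and other position sets for the over-conversion test were chosen after seeing the data. The cause of a change was not tested unless stated. All 78 values of global methylation under alternatives chosen before kept their direction; the pairwise tests of 3 libraries against 3 could not pass under any of them. Averaged radiation and BuOE differences over the common positions (0.408 and −0.846 points) did not pass, whereas those of the position-adjusted level (0.749 and −1.511) and averaged BuOE over all reported positions (−2.02) did, and radiation under BuOE was −0.165 over all reported positions. The position-adjusted interaction did not pass with at least 6 libraries (−0.483), nor did position-adjusted averaged radiation without bins of 50 or more positions (0.863). As plain means over all reported positions, the interaction (−1.392) and averaged radiation (0.531) did not pass either. With 1 library left out, position-adjusted averaged radiation ran from 0.684 to 0.840 points and did not pass without BuOE replicate 1 (0.712), BuOE replicate 3 (0.694) or BuOE+RT replicate 3 (0.700). In bins with 1 to 4 positions, the common positions gave 0.642 for radiation under BuOE, −0.885 for the interaction (not passed) and 1.084 for averaged radiation (passed), and averaged BuOE ran from −2.684 to −2.393 with 1 library left out. It passed each time when adjusted over the 6 classes. Adjusted over the 6 comparisons, it did not pass without PBS replicates 1 (−2.516), 2 (−2.606) or 3 (−2.466). The test then had fewer arrangements of labels, so these misses alone do not show a smaller difference. The interaction ran from −3.212 to −2.631 there and from −1.918 to −1.478 at 5 to 9 positions, passing each time. At 5 to 9 positions it did not pass over the common (−0.394) or all reported positions (−1.211). At 10 to 19 positions it was −0.389 and 0.055 on these sets, ran from −1.084 to −0.706 with 1 library left out, and did not pass without PBS replicates 1 (−1.025), 2 (−0.826) or 3 (−0.981), BuOE replicate 2 (−0.706), PBS+RT replicates 1 (−0.789) or 2 (−0.983) or BuOE+RT replicates 1 (−0.870) or 2 (−0.926). Radiation under PBS was −0.056 and −1.727 at 30 to 49 positions and −0.303 and −1.126 at 50 or more over the common and all reported positions. At 50 or more BuOE after radiation was 0.027 and 0.019 on these sets and averaged radiation −0.380 over all reported positions. With 1 library left out there, radiation under PBS ran from −0.056 to 0.374 and the interaction from −0.221 to 0.218. Without the level filter 5 tiles were called for radiation under BuOE and 1 for BuOE without radiation. The arcsine scale called 1 for the interaction, and the log2 ratio called 1 each for radiation under PBS, BuOE without radiation and the interaction. Leaving out 1 library gave 0 to 5 tiles in each pairwise comparison and 0 to 1 in the interaction and averaged tests (1 in each without PBS replicate 2). Radiation under PBS had 4 without PBS replicate 2 and 5, 2 and 3 without PBS+RT replicates 1, 2 and 3, and radiation under BuOE 5 and 4 without BuOE replicates 1 and 2 and 5 without BuOE+RT replicate 1 or 3. BuOE without radiation had 4 without PBS replicate 2 and 5 without BuOE replicate 1 or 2, and BuOE after radiation 2 without PBS+RT replicate 1 and 3 and 5 without BuOE+RT replicates 1 and 3. For windows, leaving out 1 library gave 9 to 125 calls for radiation under PBS, 0 to 2 for radiation under BuOE, 0 to 3 for BuOE without radiation, 490 to 941 for BuOE after radiation, 0 to 16 for the interaction, 0 to 1 for averaged radiation and 661 to 1039 for averaged BuOE. Radiation under PBS had 18, 15 and 41 calls without PBS replicates 1, 2 and 3, 9, 16 and 20 without PBS+RT replicates 1, 2 and 3, 43 without BuOE replicate 3, and 54 and 51 without BuOE+RT replicates 1 and 2. Averaged BuOE had 661 without PBS+RT replicate 1 and 695 without BuOE replicate 3, and BuOE after radiation 490 and 545 without BuOE+RT replicates 1 and 2 and 500 and 585 without PBS+RT replicates 1 and 2. The interaction had 0, 8 and 15 without PBS replicates 1, 2 and 3, 2, 1 and 16 without BuOE replicates, 1, 3 and 16 without PBS+RT replicates and 1, 4 and 10 without BuOE+RT replicates, in the same order. Radiation under BuOE had 2 and averaged radiation 1 without BuOE replicate 3, and BuOE without radiation 3 without PBS+RT replicate 1, all of them lower. Removal of each library's mean, which takes out a shift of the whole library, left 1 window for radiation under PBS, 4 for BuOE after radiation and 0 for the interaction and averaged BuOE. A minimum of 3 points left 519 windows for BuOE after radiation and 194 for averaged BuOE. Plain means gave 4 for radiation under PBS and 2 for the interaction, and bins with under 10 positions gave 541 for averaged BuOE. The 6 libraries of the comparison gave 36 for radiation under PBS and 1 for BuOE without radiation. Windows of 100 kb, with fewer positions each, gave 0, 1, 2, 1 and 1 for radiation under PBS, radiation under BuOE, BuOE after radiation (1 higher, 1 lower), the interaction (positive) and averaged BuOE. The concordance of the radiation effects was −0.1826 in windows and −0.0437 in tiles with at least 5 common positions. The 100 regroupings of windows (−0.1826 to 0.1826) could include the real grouping and swaps of its labels, so they do not test the former. The correlation of radiation under PBS with BuOE after radiation was −0.6419 in windows and −0.5761 with at least 5 common positions. In tiles it ran from −0.6431 to −0.4674 with 1 library left out. Library deviations with the same replicate number correlated by no more than 0.0646, so the numbers were not taken to pair libraries. With the replicate block, position-adjusted values were −1.041 for the interaction, 0.749 for averaged radiation and −1.511 for averaged BuOE, none of which passed (adjusted permutation p = 0.109 for the interaction and 0.1875 for the averages, where the smallest exact p is 0.03125), nor did the interaction of −0.944 at 10 to 19 positions. Averaged BuOE at 1 to 4 positions, −2.529, passed over the classes but not over the comparisons. The block gave 41 windows for radiation under PBS and 9 for the interaction, 848 for BuOE after radiation, all lower, and 976 for averaged BuOE. Not run for want of read counts were the coverage minima, edgeR, the binomial and beta-binomial models, pooled calls and extreme coverage, and not run for want of annotation were all settings for promoters, gene lists and named genes.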

Other observations

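In this part, the test by the level of the window was fixed before its result was seen, and the splits of windows by reported positions were chosen after the classes of bins had been seen.

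Windows of 1 Mb with few reported CpG positions separated the irradiated groups most. In the fifth of windows with the fewest positions, 1508 to 4032 per window over all libraries, mean levels were 70.8% in PBS, 69.9% in BuOE, 73.0% in PBS+RT and 69.2% in BuOE+RT, and BuOE after radiation differed by −3.75 points (SE 0.248; exact permutation p = 0.1). In the fifth with the most positions, 12231 to 29271, the difference was −1.76 points (SE 0.206; exact permutation p = 0.1). Radiation under PBS differed by 2.12 points (SE 0.248) in the former and 1.16 points (SE 0.206) in the latter, and radiation under BuOE by −0.720 and 0.447 points. BuOE without radiation differed by −0.916 and −1.05 points. Across 2254 windows the log2 number of positions correlated with the BuOE difference after radiation at r = 0.415 (chromosome jackknife SE 0.0285, which does not hold the spread between libraries).

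One hypothesis was that BuOE after radiation removed most methylation where fibroblasts are already less methylated, as in partially methylated domains, megabase regions of reduced methylation in cultured cells. The level in PBS libraries, which take no part in the difference, then had to correlate positively with BuOE+RT minus PBS+RT. The correlation across windows was −0.234 (chromosome jackknife SE 0.02), the opposite sign. This SE measures the spread between chromosomes of the same libraries, not between libraries, so how firm the sign is with 3 libraries per group is not known. The difference was −1.83 points (SE 0.216) in the fifth of windows with the lowest PBS level and −2.94 points (SE 0.211) in the fifth with the highest. The PBS level also correlated with the log2 number of positions at r = −0.348 (chromosome jackknife SE 0.0377), so the trend with the level was not separated from the trend with reported positions.

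On the mitochondrial genome, 195 positions common to all libraries had levels from 11.2 to 30.03% per library, with group means of 23.0% ± 6.37 in PBS, 16.6% ± 6.72 in BuOE, 19.7% ± 2.26 in PBS+RT and 20.4% ± 3.37 in BuOE+RT (SD, n = 3). The averaged BuOE difference there was −2.80 points (SE 2.92, exact permutation p = 0.385). Across the 12 libraries the mitochondrial and position-adjusted levels correlated at r = 0.149 (permutation p = 0.644). How far the mitochondrial percents reflect unconverted cytosines was not tested. At 82 common positions of the Y chromosome the levels were 75.6% ± 2.42 in PBS, 72.9% ± 1.77 in BuOE, 75.4% ± 1.11 in PBS+RT and 73.2% ± 2.12 in BuOE+RT, an averaged BuOE difference of −2.48 points (SE 1.11, exact permutation p = 0.045, adjusted p = 0.27).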
